A study of Escherichia coli K-12 with 2 samples.

How the data were processed

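RNAs that co-purified with the small RNA RybB were measured by MS2-affinity purification followed by RNA sequencing (MAPS). In this method a small RNA carries an MS2 aptamer, and the MS2 coat protein, fused to maltose-binding protein on amylose resin, retains it together with its bound RNAs. Per the labels' protocols, both strains were Escherichia coli K-12 MG1655 with the rne131 allele, which truncates the C-terminal part of RNase E, and with the chromosomal rybB gene deleted. Cultures in LB medium reached an OD600 of 0.5, and 0.1% arabinose then induced either MS2-tagged RybB or untagged RybB for 10 min. After 10 min of cooling on ice the cells were lysed in a French press and passed over resin holding 100 pmol of the coat protein fusion. RNA was eluted with maltose, treated with DNase and made into cDNA libraries with the ScriptSeq v2 kit. There was 1 library per group, so no difference between the groups had a replicate check and no p-value was computed.

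The deposited table holds, for each library, a count of reads per row, and the rows are annotated genes and the intergenic regions between 2 named genes. Reads were aligned with Bowtie, per the submitters' processing notes. Its version, the genome build, the counting program, the treatment of strand and the treatment of reads with several matches are not given in the sources used here. Reads that could belong to near-identical genes (rRNA copies, tRNA families, tufA and tufB) or to overlapping or antisense genes are therefore uncertain. The lowest count listed was 1 in both libraries, and 3612 rows (46.8%) stood at 1 in RybB against 379 (4.91%) in MS2-RybB, so a listed 1 may stand for 0 reads. The deposited table also gives, per the file headers, normalized values and the ratio of MS2-RybB to RybB. These normalized values equal the reads divided by 1 constant per library, 3408200 for MS2-RybB and 1355973 for RybB. What these constants count is not given in the sources used here, and the listed reads sum to 90.7% and 42.2% of them. The authors' deposited ratio of every row is therefore 2.15 times the ratio used below.

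The table has 7725 rows, of which 4429 are genes and 3296 are intergenic regions. Gene names were matched to the RefSeq gene table of assembly ASM584v2, which gave a current symbol for 4405 gene rows, 4014 of them by the same symbol, 166 after removal of a prime and 225 through a synonym. As the files name no build, no coordinates are given. Names in the text are those of the table, with the current symbol beside them where it differs.

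Reads were divided by each library's total over all rows, which is 3089779 for MS2-RybB and 572447 for RybB, and multiplied by 1000000 (CPM). Intergenic rows entered these totals because each names the genes beside it, and the total over gene rows alone was tried as an alternative. The ratio of a gene is its CPM in MS2-RybB over its CPM in RybB. Its 95% interval comes from the exact Clopper-Pearson interval of the share of the gene's reads that lie in MS2-RybB. Reads carry no molecular identifiers here, so amplification copies of 1 molecule count as separate reads. All intervals cover the counting error of reads only and may be too narrow. A single read is worth 0.324 CPM in MS2-RybB and 1.75 CPM in RybB. A row was eligible with 50 or more reads in the library where it had more. An eligible gene was called enriched at a ratio of 4 or more and depleted at a ratio of 0.25 or less, a fixed rule of size in place of a test. For each of 15 gene lists the median log2 ratio of the eligible members was computed with 0.5 reads, shared out by library size, added to each library. Its percentile was taken among 10000 random lists of the same size matched on mean CPM in 20 bins. That mean includes the MS2-RybB reads, so the matching is not independent of the ratio. This percentile describes these 2 libraries, and it was also computed with mean CPM and ratios under each other scaling, an alternative chosen after seeing the data.

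The grouping, the rule of size, the gene lists, the genes to be named and most alternatives were fixed before the data were examined. The named genes are rybB, all members of the lists of reported RybB targets and of the glyW-cysT-leuZ transcript, the 25 eligible genes with the highest ratio and the 8 with the lowest, and the 2 highest and 2 lowest eligible members of each other list. Intergenic regions, operons and the other single genes named were chosen after their values were seen. The alternatives fixed beforehand were other scalings (totals without rRNA and tRNA genes, totals without rybB, median of ratios, TMM from edgeR), read minimums of 10, 200 and none, thresholds of 2-fold and 10-fold, whole intervals past the threshold, the authors' deposited ratio, and 1 or 5 reads added to each library. Leaving out replicates and testing other splits of the samples do not apply with 1 library per group.

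The scripts were tested on simulated reads for all 4429 genes of this comparison, with 200 genes changed. These 200 were drawn only from genes whose expected MS2-RybB reads, before the change, lay above the read minimum. All 50 genes raised 8-fold, all 50 raised 16-fold, all 50 lowered 8-fold and all 50 lowered 16-fold were called, and 0 of 1319 unchanged eligible genes were. The intervals covered the simulated ratio in 95.7% of genes. The simulation held counting error only, used folds of 8 and 16 against a threshold of 4, and set no floor of 1. It checks the scripts and gives no error rate for these libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 gave the TMM factors.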

Results

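RNAs purified with MS2-tagged RybB were compared with RNAs retained from cells that made untagged RybB, the control of the series. RybB is a small RNA of the envelope stress response that pairs with mRNAs of outer membrane proteins with the help of Hfq. The comparison asks which RNAs co-purified with RybB through the MS2 tag. The series holds no library of input RNA. A ratio may therefore also reflect a difference in RNA abundance between the cultures. Each group had 1 library, so no difference below has a replicate check, and the intervals given are 95% counting intervals. The MS2-RybB library held 3089779 reads in the table and the RybB library 572447. rRNA genes took 63.8% of the reads in MS2-RybB and 68.9% in RybB, tRNA genes 1.97% and 0.0996%, and intergenic regions 10.4% and 7.61%. Most of the 60851 tRNA reads in MS2-RybB came from 3 genes, leuZ with 25824, glyW with 19201 and cysT with 8945. The median eligible gene had 134 reads in MS2-RybB and 8 in RybB, so the control's reads set the precision of most ratios.

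The rybB gene had 162 reads in the library labelled MS2-RybB and 27 in the library labelled RybB, a ratio of 1.11 (0.736 to 1.74), and ranked 1470 among 1790 eligible genes. Its side of 1 depended on the scaling, with 0.363 (0.241 to 0.568) under the median of ratios, 0.736 (0.488 to 1.15) under TMM and 2.39 (1.58 to 3.73) under the authors' constants. It reached the threshold of 4 under none of the scalings tried. The region between rybB and ybjL had 80 and 27 reads, a ratio of 0.549 (0.351 to 0.884). Only the RybB of the MS2-RybB library carried the aptamer, so the ratio of this row need not measure how well the bait was recovered.

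Reported RybB targets were enriched to very different degrees, and ompW, ompC and tsx ranked 4, 11 and 24 among the 1790 eligible genes. The mRNA of OmpW, a small outer membrane channel, had 23500 reads in MS2-RybB and 17 in RybB, a ratio of 256 (160 to 440). That of the major porin OmpC had 61073 and 120 reads, a ratio of 94.3 (78.8 to 114). The nucleoside channel gene tsx had a ratio of 54.6 (34.5 to 92.2) and the ribokinase gene rbsK one of 42.4 (25.2 to 77.6). Of the 13 reported targets, 10 were eligible and 9 of these were enriched, against 41.1% of all eligible genes. The count was 6 under the median of ratios, without ompF, lamB and nmpC', 8 under TMM and with totals without rRNA and tRNA genes, in both without ompF, and 10 under the authors' constants, with ompA.

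The other enriched targets had lower ratios. They ranked from 166 for fadL to 731 for ompF. The fatty acid transporter gene fadL stood at 16.9 (6.53 to 62.2) and the pseudouridine synthase gene rluD at 13.7 (5.28 to 50.5), each with 4 reads in RybB. The porin pseudogene nmpC, listed as nmpC', stood at 9.95 (8.44 to 11.8) and the maltoporin gene lamB at 7.18 (5.09 to 10.5). The porin gene ompF had a ratio of 4.05 (3.10 to 5.40), an interval that included the threshold. The ompA gene had 13650 and 819 reads and a ratio of 3.09 (2.88 to 3.32), short of the threshold, whereas the region between ompA and sulA had 41773 and 604 reads and a ratio of 12.8 (11.8 to 13.9). ompN, fiu and csgD had at most 18 reads and were not eligible. The median log2 ratio of the 10 eligible targets was 3.87, at percentile 99.8 of matched random lists, whose typical median was 0.36. The matching used the CPM of both libraries, so the enrichment of a target helped set the genes it was matched to. The percentile is therefore not independent of these ratios. Without rbsK and rluD, an alternative chosen after seeing the data, the median of the 8 remaining was 3.67, at percentile 99.6. Whether some of the listed targets were first picked from these libraries was not checked.

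**Figure D1:**
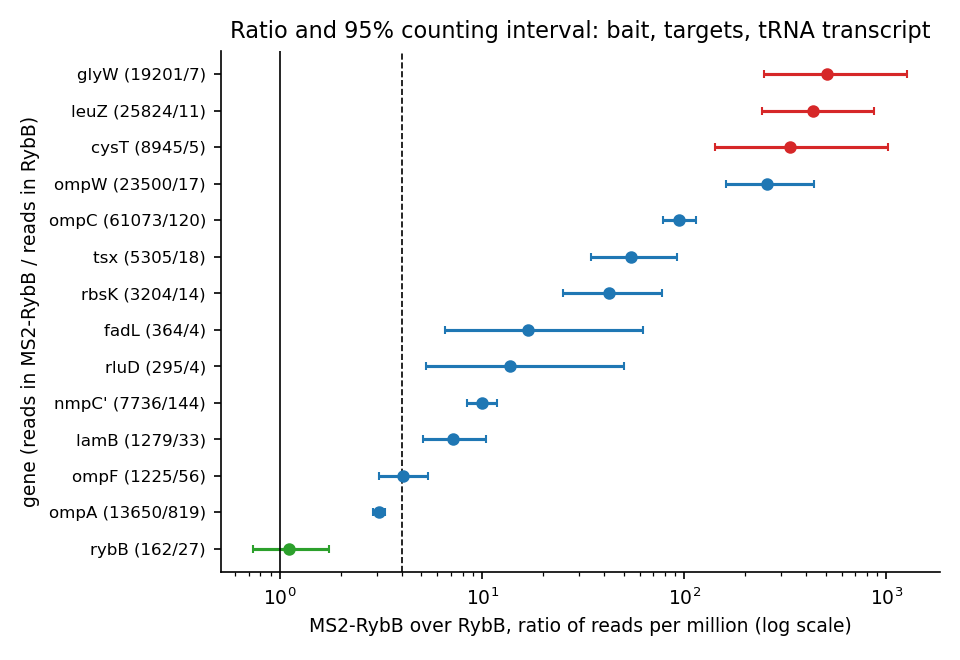
Ratio of CPM in MS2-RybB over RybB (log axis, 1 library per group) for the bait rybB (green), the 10 eligible reported targets (blue) and glyW, cysT and leuZ (red). Bars are 95% counting intervals, labels give the reads in each library, and the lines mark ratios of 1 and 4; rybB lies at 1.11 and ompW at 256.

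Genes of the glyW-cysT-leuZ tRNA transcript had the 3 highest ratios of all eligible genes. The ratio was 508 (247 to 1264) for glyW, 435 (243 to 871) for leuZ and 331 (142 to 1021) for cysT. All 3 genes were enriched. The place of cysT above ompW is not firm, as their intervals overlap. With 5 reads added to each library cysT stood at 166 and ompW at 198. This transcript is known from the study itself, so the list is not independent evidence of its direction. The 4 regions beside and between these genes had ratios of the same order, from 297 (157 to 650) for the region between cysT and glyW to 1013 (182 to 40028) for that between glyW and pgsA, which had 1 read in RybB. The 7 rows from the yecA-leuZ region to the glyW-pgsA region together held 99419 reads in MS2-RybB, which is 3.22% of that library (exact interval 3.20 to 3.24). They held 44 reads in RybB, or 0.00769% (0.00558 to 0.0103), a ratio of 419 (312 to 576). Ratios were lower further out, with 49.7 (16.9 to 241) for yecA, 51.8 (14.3 to 429) for pgsA, 12.0 (3.27 to 100.5) for uvrC and 6.60 (2.77 to 20.6) for uvrY.

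**Figure D2:**
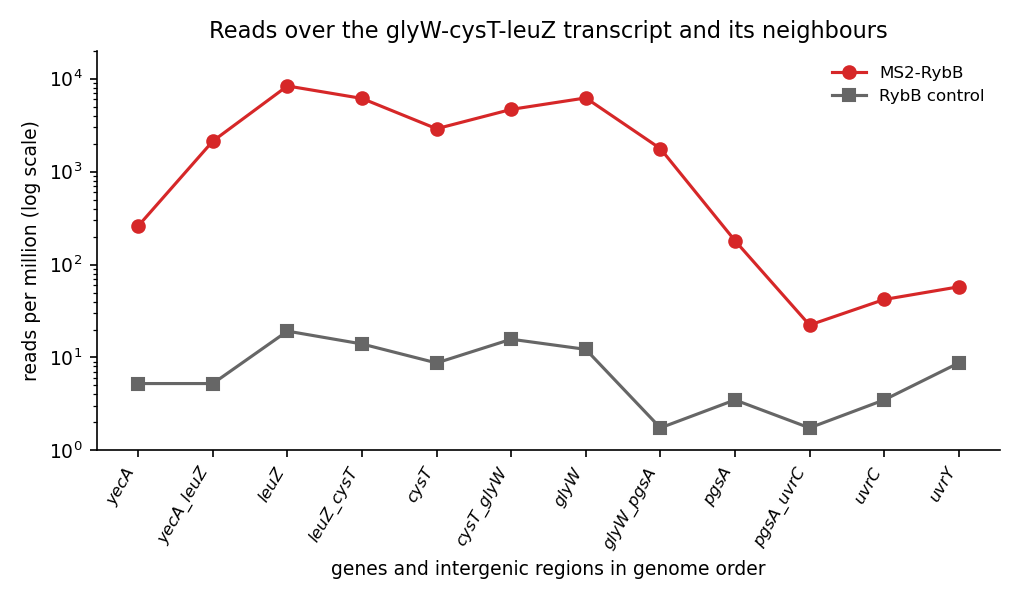
CPM (log axis, not corrected for length) in MS2-RybB (red circles) and RybB (grey squares), 1 library each, over genes and intergenic regions in genome order. In MS2-RybB the rows from the yecA-leuZ region to the glyW-pgsA region lie between 1770 and 8358, and in RybB no row exceeds 19.2.

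Over all genes, 735 of 1790 eligible genes were enriched (41.1%), 34 were depleted (1.90%) and 1021 lay between the thresholds. The median ratio was 3.06 over all eligible genes but 0.645 over the 255 with 50 or more reads in RybB, and both values carry their selection, as the others passed the read minimum only in the deeper MS2-RybB library and those 255 were picked by their control reads. The 25 highest ratios belonged to 5 tRNA genes, 3 reported targets and 17 other genes, and ran from 52.0 to 508. Besides the tRNAs named above, metW stood at 220 (39.4 to 8701) and metV at 103 (18.5 to 4091), each with 1 read in RybB. yifE, now maoP, a gene for a macrodomain organisation factor, stood at 157 (53.6 to 761). rcnB, which acts in nickel and cobalt homeostasis, stood at 136 (24.4 to 5386). The adjoining genes rsmH, a 16S rRNA methyltransferase, and ftsL, a cell division protein, stood at 118 (50.3 to 362) and 80.0 (34.2 to 247). The genes smg, yrdD and yrdB stood at 90.7 (31.0 to 440), 106 (19.0 to 4208) and 55.4 (9.87 to 2195). yciM, now lapB, which regulates lipopolysaccharide synthesis, stood at 52.0 (22.2 to 160), and syd, whose product binds SecY, at 62.7 (17.3 to 519).

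The remaining 8 of the 25 each had 1 read in RybB, and their ratios ran from 58.9 (10.5 to 2334) for the chitoporin gene chiP to 77.6 (13.9 to 3073) for the hydroxysteroid dehydrogenase gene hdhA. They also include ymbA, now pqiC, uspD, opgC, the glyoxalase gene gloB, yacG and the ribosome rescue gene arfB. All 25 had intervals wholly above 4, with a lowest bound of 9.87. These 25 were picked as the highest ratios of the same libraries, so bounds above 4 follow from the choice and are no separate check. For 13 of the 25 the RybB count was a listed 1, which may be a floor of the table. Of the 735 enriched genes, 396 had 3 or fewer reads in RybB, and 243 had an interval wholly at or above 4. The split of calls depended on the scaling, with 526 enriched and 89 depleted under TMM, 246 and 214 under the median of ratios, and 1210 and 9 with the ratio of the authors' deposited table.

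**Figure D3:**
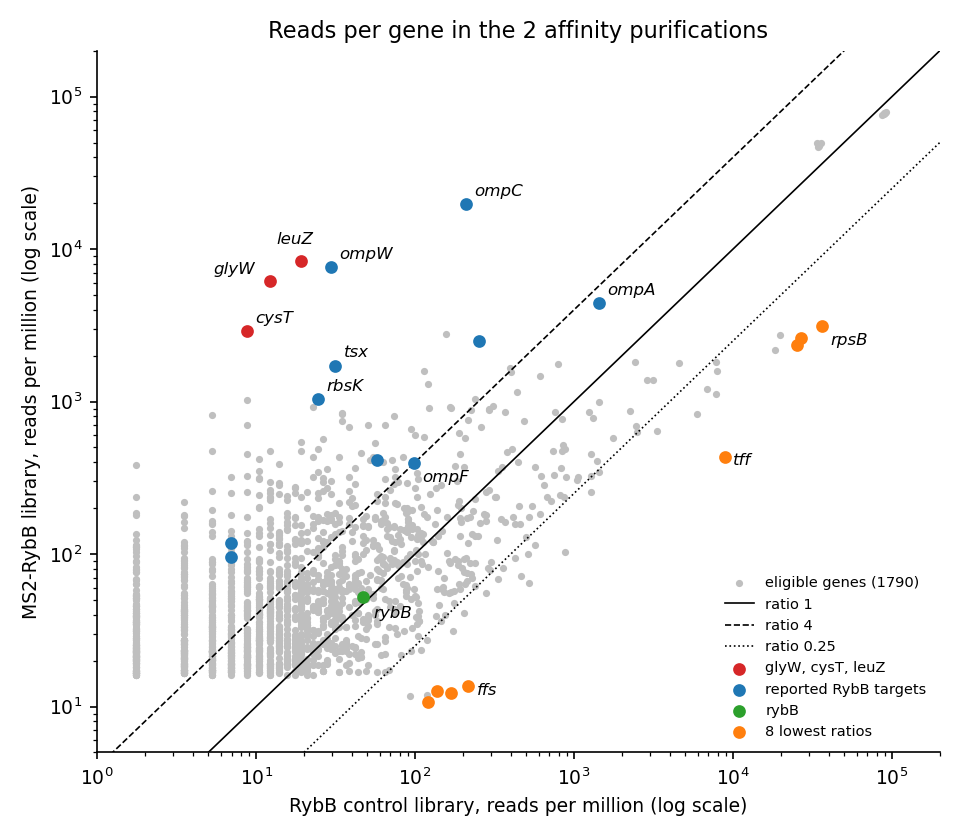
CPM of the 1790 eligible genes in RybB (x, log axis) and MS2-RybB (y, log axis), 1 library each, with lines at ratios of 1, 4 and 0.25. glyW, cysT and leuZ (red) and the reported targets (blue) lie above the ratio of 1, rybB (green) lies near it at 1.11, and the 8 lowest ratios (orange) run from 0.0489 to 0.0973.

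Of 598 eligible intergenic regions, 322 were enriched and 18 were depleted. Besides the tRNA transcript, the highest was the region between yciC and ompW at 764 (137 to 30164), with 4121 reads and 1 read. The region between hdfR and yifE stood at 322 (57.7 to 12726) and that between metZ and metW at 263 (47.1 to 10384). The region between ompC and micF held 15248 and 28 reads, a ratio of 101 (69.8 to 152). The region between malK and lamB, with 1950 and 7 reads, stood at 51.6, and that between tsx and yajI at 44.8 (26.2 to 84.2). The lowest was the region between tff and rpsB, at 0.0483 (0.0441 to 0.0529) with 610 and 2338 reads.

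The depleted genes included some of the most counted mRNAs of the control. rpsB, the gene of ribosomal protein S2, had 9633 reads in MS2-RybB and 20690 in RybB, a ratio of 0.0863 (0.0842 to 0.0884). The small RNA gene tff beside it had the lowest ratio of all, 0.0489 (0.0460 to 0.0520). ffs, the RNA of the signal recognition particle, stood at 0.0628 (0.0431 to 0.0897) and narX, a nitrate sensor kinase, at 0.0915 (0.0607 to 0.136). The rRNA genes rrfF, rrfD, rrlD and rrlG stood at 0.0733, 0.0886, 0.0932 and 0.0973, and the counts of such near-identical copies are uncertain. All 8 of these lowest genes stayed below 0.25 under every scaling tried, the authors' constants included. This follows from their low ratios, as the largest scaling factor was 2.15, and is no separate check.

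Ribosomal protein genes as a group lay below matched random lists. Of 50 eligible members, 6 were depleted and 4 enriched, and 16 had intervals above 1 and 19 below 1. Their median log2 ratio of -0.14 (95% interval -0.46 to 0.45) was at percentile 0.23 of random lists, whose typical median was 0.98. The 6 depleted members were rpsB and 5 genes of the S10 operon. Genes of 1 operon are not independent, which the percentile leaves out. rplD stood at 0.119 (0.115 to 0.123), whereas rplU and rpsU stood at 13.8 (9.60 to 20.7) and 11.5 (3.11 to 95.9). Under the authors' constants the sign of this median turned positive, at 0.97. Of 21 eligible rRNA genes none was enriched and 6 were depleted (median log2 ratio -1.13, percentile 1.09). The 6 were rrsD, rrsG, rrlD, rrlG, rrfD and rrfF, and the 16S and 23S genes of the other 5 operons stood between 0.861 and 1.46. These rows are near-identical copies of a few RNAs, so they are not independent members of the list. The median over rows is also not the change of rRNA as a whole. All rRNA genes together took 63.8% of reads in MS2-RybB and 68.9% in RybB. For the 16 rRNA genes with 200 or more reads the median was -0.21, at percentile 63.6. The 16S genes rrsA and rrsB stood at 1.46 (1.44 to 1.48) and 1.40 (1.38 to 1.42), values that were under 1 with TMM and the median of ratios. The other stable RNAs had 4 eligible members, none enriched and 1 depleted (ffs), and a median of -0.48 at percentile 4.27. This median turned positive under the authors' constants, at 0.62, and for the 2 members with 200 or more reads, at 0.14 (percentile 16.4). rnpB, the RNase P RNA, stood at 1.25 (0.900 to 1.77), ssrA, the transfer-messenger RNA, at 0.969 (0.805 to 1.17), and ssrS, the 6S RNA, at 0.525 (0.325 to 0.874).

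tRNAs outside the glyW-cysT-leuZ transcript split widely. Of 28 eligible members 10 were enriched and none depleted, with metW and metV highest, valY at 0.363 (0.255 to 0.523) and valX at 0.371 (0.233 to 0.600) lowest. Their median log2 ratio of 0.83 was at percentile 1.68, and at percentile 88.7 for the 7 members with 200 or more reads. Of 24 listed Hfq-binding small RNAs other than RybB, 23 were in the table and 4 were eligible. arcZ and spf were enriched at 6.30 (2.10 to 31.1) and 6.24 (2.07 to 30.8), fnrS was depleted at 0.126 (0.0800 to 0.196), and gcvB stood at 0.526 (0.434 to 0.641). The median of these 4, 0.83, was at percentile 25.4. For the 11 members with 10 or more reads, 5 enriched and 1 depleted, it was at percentile 46.4. Of all genes tested at that minimum 28.0% were enriched.

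Of 12 eligible outer membrane protein genes not listed as targets, 7 were enriched and 1 was depleted. chiP and fepA, the enterobactin receptor gene, were highest, with fepA at 9.45 (1.62 to 380) on 1 read in RybB. tolC, the outer membrane efflux channel gene, was depleted at 0.155 (0.129 to 0.186), and the lipoprotein gene lpp stood at 0.867 (0.663 to 1.15). Their median log2 ratio of 2.18 was at percentile 84.1. Of 16 eligible genes of the sigmaE regulon, the envelope stress regulon, 5 were enriched and none depleted. The periplasmic chaperone gene skp stood at 23.6 (15.2 to 38.6) and bamE at 12.2 (2.12 to 490), and yraP, now dolP, and yeaY stood at 0.339 (0.262 to 0.441) and 0.340 (0.247 to 0.473). The median of this list, 1.13, was at percentile 12.9, but at 46.9 for the 20 members with 10 or more reads and at 85.9 for the 5 with 200 or more.

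Metabolic and induction lists lay near matched random lists at the main read minimum. Of 11 eligible TCA cycle genes 2 were enriched, icd at 7.23 (3.62 to 16.9) and fumB at 5.32 (2.54 to 13.4). fumA and acnB stood at 0.751 (0.562 to 1.02) and 1.20 (0.842 to 1.75). The median of 1.19 was at percentile 29.0, but at 9.62 for the 8 members with 200 or more reads. Of 9 eligible genes of the arabinose regulon, whose sugar induced both constructs, araJ was enriched at 6.39 (3.84 to 11.5). araC, araG and araB stood at 3.75 (2.78 to 5.18), 1.19 (0.967 to 1.47) and 0.933 (0.733 to 1.20), and the median of 1.08 was at percentile 36.6. Of 7 eligible maltose genes, malK and malG were enriched at 11.0 (8.09 to 15.2) and 5.28 (1.40 to 44.7), malT and malQ stood at 1.18 (0.724 to 2.03) and 1.11 (0.747 to 1.71), and the median of 1.83 was at percentile 50.1.

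Among 10 genes of RNA decay enzymes and Hfq, 3 were enriched and none depleted. The RNase R gene rnr stood at 14.0 (8.17 to 26.5) and rppH, the RNA pyrophosphohydrolase gene, at 11.8 (5.01 to 36.7), against 1.05 (0.901 to 1.22) for rne and 1.53 (0.938 to 2.66) for rhlB. Their median log2 ratio of 1.29 was at percentile 32.1. Iron uptake had 2 eligible genes of 20, feoA at 1.48 (0.674 to 3.85) and feoB at 0.903 (0.523 to 1.66), with a median of 0.21 at percentile 2.48. This percentile was 6.8 for the 7 members with 10 or more reads and 12.7 with as many genes picked by mean CPM. Flagella and chemotaxis had 1 eligible gene of 23, tsr at 0.982 (0.494 to 2.16), whose log2 ratio was -0.03 (percentile 3.78). With a minimum of 10 reads 17 members entered, 5 enriched and 1 depleted, and their median of 0.84 was at percentile 38.0.

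**Figure D4:**
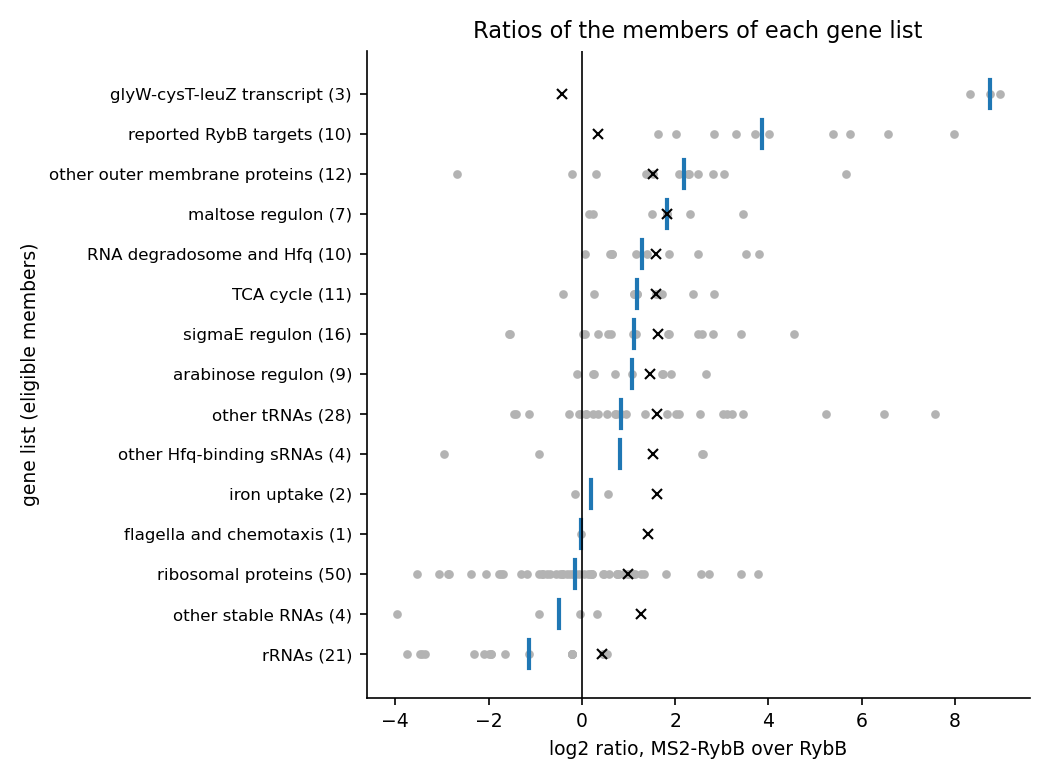
Log2 ratio of MS2-RybB over RybB (x, 1 library each) for the eligible members of each gene list (grey points; numbers in brackets), with the list median (blue bar) and the typical median of 10000 matched random lists (cross). The reported targets have a median of 3.87 against 0.36 for random lists, and ribosomal proteins one of -0.14 against 0.98.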

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

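The authors' constants, the total of gene rows, the filter on mean CPM, the reading of a listed 1 in RybB as 3 reads, the targets without rbsK and rluD, and the alternatives for intergenic regions were chosen after seeing the data. Scaling shifts every log2 ratio by -1.61 under the median of ratios, -0.59 under TMM, -0.14 with totals without rRNA and tRNA genes and 1.10 under the authors' constants. The control's depth also limits the ratios, as 1 of its reads is worth 1.75 CPM.

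The median ratio of eligible genes, 3.06, was 2.77 without rRNA and tRNA genes, 1 by construction under the median of ratios, 2.03 under TMM, 6.57 under the authors' constants, 2.64 and 1.75 with 1 and 5 reads added, and 2.54 for as many genes picked by mean CPM. It was also 0.645 over genes with 50 or more RybB reads. The 735 enriched and 34 depleted genes became 246 and 214 under the median of ratios, 1210 and 9 with the authors' deposited ratio, and 305 and 22 at a minimum of 200 reads. At 2-fold they were 1168 and 128, and at 10-fold 327 and 8. Depleted genes numbered 89 under TMM and 131 without a minimum, and enriched genes 243 with the whole interval past the threshold. Depleted intergenic regions, 18, numbered 5 with the authors' deposited ratio. Changes with scalings, thresholds, added reads and filters follow from their construction, since a scaling multiplies every ratio by 1 factor. The other 15 counts stayed within 1.5 times.

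The median log2 ratio of the reported targets lay between 2.26 and 4.97 under all alternatives tried, and their percentile lay between 99.6 and 99.9 under the read filters, with 5 reads added and without rbsK and rluD, and was at least 99.3 under the scalings. Percentiles of the other lists moved more with the scaling, except that of the glyW-cysT-leuZ transcript, which stayed at 99.965. The range was 36.6 to 71.5 for the arabinose regulon, 12.9 to 34.0 for the sigmaE regulon and 0.215 to 10.9 for rRNA genes. Ribosomal proteins stayed at or below 5.71. Of 164 alternative values of list medians, 142 stayed inside the 95% interval of the median, or, for lists with under 6 eligible members, inside the range of the members (the counting interval for a single one). Some of these could hardly move, as totals without rybB shift log2 ratios by 7.6e-06 and the total of gene rows by 0.045. This count therefore also reflects the choice of alternatives and the width of the intervals. The sign differed for 7 of 15 lists under the median of ratios, 3 under the authors' constants, and 1 each under TMM and with the total of gene rows. It also differed for 2 of the 13 lists left at 200 reads (other Hfq-binding small RNAs, other stable RNAs), 2 without a minimum (flagella, other tRNAs) and 1 at 10 reads (flagella). Of 45 named genes with a ratio of 4 or more, 31 kept it under the median of ratios, 42 under TMM and 37 with 5 reads added. Of 11 at or below 0.25, 8 kept it under the authors' constants. No named gene called enriched or depleted changed its side of 1. Under the scalings none could, as factors of 0.327 to 2.15 cannot undo a 4-fold difference, so this is no separate check.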

Other observations

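The tests of rybB, of the rRNA copies and of tufA and tufB were chosen after their values were seen, and that of adjoining rows before. Operons were also picked after their values were seen, and are described here without an explanation. In the division and cell wall cluster 9 of 15 eligible genes were enriched. The ratios of rsmH, ftsL and ftsI were 118 (50.3 to 362), 80.0 (34.2 to 247) and 40.5 (23.7 to 76.2), those of murF and ftsZ 1.07 (0.545 to 2.36) and 0.937 (0.652 to 1.38), and ddlB and ftsQ between them stood at 19.5 (9.39 to 48.6) and 20.1 (11.9 to 36.8). In the ribose operon 5 of 6 genes were enriched, with rbsD at 21.3 (13.7 to 34.9) and rbsB at 17.8 (14.5 to 22.2), while rbsA stood at 1.97 (1.41 to 2.82). The first genes of the fumarate reductase, dimethyl sulfoxide reductase and type 1 fimbriae operons were enriched, frdA at 13.9 (10.9 to 18.0), dmsA at 40.2 (18.4 to 110) and fimA at 9.75 (5.97 to 17.1). frdB and frdC stood at 3.89 (2.74 to 5.70) and 2.65 (1.67 to 4.47), and fimI and fimD at 2.24 (1.18 to 4.79) and 0.893 (0.461 to 1.90). dmsB stood at 7.78 (1.32 to 315) on 1 read in RybB and fimC at 3.21 (1.04 to 16.1), wide intervals that overlap those of the first genes.

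Other operons held depleted genes or low ratios. The 11 genes of the S10 ribosomal protein operon made up 0.844% of reads in MS2-RybB and 5.28% in RybB, and the 5 depleted ones were rpsJ, rplC, rplD, rplW and rplB, with ratios of 0.138, 0.138, 0.119, 0.193 and 0.239. The 3 genes tff, rpsB and tsf made up 0.467% and 5.29%. All 3 eligible nitrate reductase genes, narG, narH and narJ, were depleted at 0.207, 0.182 and 0.101, as were deoB and deoD of nucleoside breakdown at 0.117 and 0.125, whereas deoC, not eligible, stood at 0.926 (0.405 to 2.47). In the galactose operon galT and galM were depleted at 0.199 and 0.224, and none of 9 genes of the ATP synthase operon was, with ratios from 0.254 (0.237 to 0.273) for atpA to 1.78 (0.861 to 4.28) for atpI.

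The bait rybB did not reach the enrichment threshold of 4, with a ratio of 1.11. No scaling tried brought it there, since the highest ratio, under the authors' constants, was 2.39 (1.58 to 3.73), although that interval lies above 1. Counting error of reads alone did not bring it to 4 either, as its interval with table totals ended at 1.74. Such intervals leave out amplification copies and differences between replicates and may be too narrow, so too few sampled molecules are not excluded. The 34 other eligible gene rows of 100 nt or less had a median ratio of 2.69, above the interval of rybB and below the 3.06 of all eligible genes, with single rows from 0.363 to 508. These rows include glyW, cysT and leuZ, and the region between leuZ and cysT itself held 18954 reads in MS2-RybB. The length of a row need not be that of its RNA, so this set cannot settle how short RNAs were recovered. Whether short RNAs were separated poorly in both libraries thus stays open, and no biological explanation was tested. The bait was also not the same RNA in both libraries, as only the MS2-RybB strain made it with the aptamer. How reads holding aptamer sequence were counted is not given in the sources used here. The ratio of rybB therefore does not show whether the bait was retained.

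The 16S and 23S rows of the D and G rRNA operons were far lower than those of the other 5 operons, above all in MS2-RybB. In MS2-RybB their highest row held 3.87% of the lowest other copy for 16S and 3.45% for 23S, against 23.4% and 30.7% in RybB. By their row names, looked up afterwards, these are the 2 of 7 operons listed with 23S before 16S, a match that 1 of 21 choices of 2 operons gives (4.76%). Placement of reads of near-identical copies by orientation may account for this, though other differences between these operons were not separated from it, and tufA, listed in inverted order, stood at 0.436 (0.371 to 0.515) against 2.22 (2.02 to 2.45) for its near-identical copy tufB, 5.10 times more, a single pair that had to go one way or the other. No biological explanation was tested, and the ratios of rrlD, rrlG, rrsD and rrsG stay open to this reading. The depleted rows rrfD and rrfF were not part of this comparison, and their counts stay uncertain as well.

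Enriched genes adjoined enriched intergenic regions. Of 372 enriched genes with an eligible adjoining region, 329 (88.4%) had an enriched one, against 119 of 415 (28.7%) other eligible genes. The difference of 59.8 percentage points passed the 20 set beforehand. Reads of 1 RNA that spread over adjoining rows may account for part of the 735 enriched genes, but this was not shown. Neighbours such as yecA and pgsA beside the tRNA transcript need not be separate partners. Overlap between adjoining RNAs that bind independently was not tested.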
